A study of Mus musculus with 4 samples.

How the data were processed

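The series holds 4 RNA sequencing libraries of mouse liver, 2 from mice with a Dicer1 mutation and 2 from wild-type mice, all 4 weeks old. Per the labels' protocols, total RNA was treated with DNase and made into stranded libraries with a dUTP second strand, from fragments chosen by size. The protocol names a TruSeq kit and NEB reagents side by side, and which kit was used is not settled here. Groups and replicate numbers come from the titles and the genotype label, and the design text speaks of separate mice.

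Per the file headers, the authors ran StringTie 2.1.3b on each library against the NCBI RefSeq annotation release 108 of mm10, in the mode that estimates reference transcripts and assembles no others, with the setting for reversed stranded pairs. Per the submitters' processing notes the tools were Bowtie2 2.0.6 and TopHat2 2.0.9, while the path of the aligned reads in the file headers names a HISAT folder; which aligner made the values is therefore open. The deposited files give TPM (transcript abundance corrected for length, with the same total in each library), FPKM and mean read coverage for each of 129299 transcripts, and mean coverage for each exon, as text attributes. No read counts are among the deposited values used here, so the main comparison uses no count model; voom on reads estimated from coverage was run as an alternative.

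TPM and FPKM were summed over the transcripts of each of 45777 gene identifiers. Of these, 45679 were matched to a symbol by gene identifier in the RefSeq table of GRCm38.p6, and 44024 had the same start and end there as in the files; GRCm38 and mm10 are the same assembly, so coordinates are given as in the files. Depth was estimated from the ratio of coverage to FPKM, which is constant within a library. It gave 3.70 and 3.88 gigabases for the mutants and 3.53 and 4.32 gigabases for the wild types. Steps of 202 bases in the lowest coverage values fit pairs of 101-base reads. At these depths 1 such pair on a 2000-base transcript is worth 0.0487 to 0.0606 TPM, so values near that level rest on single pairs. Mitochondrial transcripts took 19.2% to 21.6% of TPM.

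Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 0.5), for genes with a mean of at least 0.5 TPM over the 4 libraries, with moderated variances that follow a trend in mean level, genotype as the sole term, and Benjamini-Hochberg adjustment at 0.05, two-sided. Fold changes are on that log2 scale, which understates the change of genes near 0. With 2 against 2 the smallest two-sided exact permutation p is 0.33, so calls on single genes rest on the spread that limma pools over genes. Between-group scaling of TPM was left as deposited.

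Before the data were examined, 52 gene lists for liver cell types, hepatocyte functions, fetal genes, cilia, signalling, cell cycle, stress, inflammation, microRNA targets and technical checks were fixed. The 48 lists with at least 5 tested genes went through camera with a preset correlation of 0.01, and again with a correlation estimated per list and with fry. Camera compares a list with all other genes, and fry asks whether the genes of a list move 1 way from 0 on balance. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries and not from the number of genes. Few lists can pass that run, whatever their correlation. The naming rule, also fixed beforehand, takes per direction the 10 genes with the largest change among those past the threshold whose groups do not overlap, leaving out predicted-gene symbols, then Dicer1, and up to 4 genes with the smallest p from each list. Some genes that the rule takes are not reported here.

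For microRNA sites, the longest annotated 3′ UTR of 12480 protein-coding genes was taken from GENCODE vM21 on the same assembly. For every 7-mer the mean log2 change of genes with the site was compared with that of genes without it, after regression on UTR length, GC content and mean expression. The sites of 11 abundant 5p and 10 abundant 3p microRNAs, fixed beforehand, were then ranked, and the mean z of both strands compared by a two-sided permutation test with 100000 resamples. Genes of 1 family are not independent in this z.

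Exon depth of Dicer1 was summed over the gene's annotated transcripts and divided by the aligned gigabases of the library. The plan named the main transcript alone; the sum was used because the transcript with the highest estimate differs between libraries.

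The tests across genes were first tested on simulated data. With values drawn from the real wild-type means and the fitted spread (13789 genes in that step), limma called 0 of 50 genes changed by 1 on the log2 scale, 27 of 48 changed by 2, 41 of 49 changed by 3 and 42 of 48 changed by 4, and 5 of 13594 unchanged genes. In that limma step few genes were changed, so the Benjamini-Hochberg adjustment was stricter than in the real fit, which called 3038 of 14792 genes. The real fit also called changes below 1, such as Lyve1 (-0.74), so the simulated counts do not measure its sensitivity. Camera called the 1 raised list of 25 genes and 0 of 47 random lists. Each gene was drawn independently there, whereas genes of the real lists can move together (estimated correlation 0.951 for G2, M phase and mitosis). The 0 of 47 therefore does not show how often camera with the preset correlation calls such lists falsely. In the site test, a shift of 0.3 added to the genes with the miR-122-5p site was ranked 1 (12480 genes). For exon depth, 200 of 3812 simulated genes were given 5 exons raised 8-fold in both mutants: 151 of them, and 0 of the other 3612, had a spread of exon ratios as large as that of Dicer1.

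The alternatives tried were FPKM for TPM, pseudocounts of 1 and 0.1, no filter, a mean of at least 2, quantile normalization, median-of-ratios factors, rescaling without the 20 most abundant genes, 3 other variance models of limma (no trend, a robust trend, vooma weights), the replicate number as a block, an adjusted p of 0.10, and each library left out. After the data had been seen, limma's voom on reads estimated from coverage, a rescaling to nuclear protein-coding genes and the site comparison without miR-122 and let-7 were added. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the other steps.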

Results

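Liver RNA from 4 mice, all 4 weeks old and of a C57BL/6 background, was sequenced as stranded mRNA libraries, 2 from animals with a mutation in Dicer1 and 2 from wild-type animals. Dicer1 encodes the ribonuclease that cuts microRNA hairpins into mature 5p and 3p strands, and the labels do not give the position of the mutation. The comparison asks how the transcripts of the liver differ between the genotypes at this age. The deposited values are TPM, transcript abundance corrected for length and scaled to the same total in each library, and were summed here per gene. Aligned bases came to 3.70 and 3.88 gigabases in mutants 1 and 2 and to 3.53 and 4.32 gigabases in wild types 1 and 2. Between 18460 genes (wild type 1) and 20705 genes (mutant 2) had a value above 0. Across the 14792 genes tested, Pearson's r of log2 values was 0.956 between the mutants, 0.985 between the wild types, and 0.891 to 0.922 between groups; these correlations are across genes, which are not independent replicates. Xist, the transcript of the inactive X chromosome, was between 94.1 and 116 TPM in the 4 libraries, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were listed at 0 in each. By these values all 4 mice were female, so the groups did not differ in sex.

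The summed value of the Dicer1 gene was not called different between the groups, and 5 of its exons carried much of it in the mutants. Dicer1 (chromosome 12, 104687740 to 104751968 on the minus strand, mm10) was at 15.6 and 6.88 TPM in the mutants and at 5.75 and 5.39 TPM in the wild types. The log2 difference was 0.85 with an SE of 0.39 (n = 2 per group; limma, Benjamini-Hochberg adjusted p = 0.165) and did not pass the test. Read depth along the 27 exons of the RefSeq transcript was uneven in both mutants. Exon 5 (104729128 to 104729262, coding) had 102 and 20.03 reads of depth per aligned gigabase in the mutants, against 2.41 and 2.58 in the wild types. Exon 24 (104694478 to 104694746, coding) had 44.6 and 10.7 in the mutants, against 2.35 and 2.62. Exons 2, 4 and 18 were raised in the same way, with log2 ratios of mutant to wild-type mean depth of 3.24, 2.84 and 2.39. The other 22 exons had a median log2 ratio of -0.17, with median depths of 2.15 and 2.48 in the mutants, below the 2.95 and 3.24 in the wild types; among them exon 10 had a ratio of -1.23 and exon 9 of 1.48. These 5 exons held 63.0% and 31.3% of the Dicer1 exon bases in mutants 1 and 2, and 10.3% and 10.1% in the wild types. No test was made of exon depth, and the limit for a raised exon, a log2 ratio of 2 with both mutants above both wild types, was set after the depths were seen. Without mutant 2, the Dicer1 difference passed the test (log2 difference 1.41; limma, Benjamini-Hochberg adjusted p = 0.0433), and the value then rests on mutant 1 alone; without mutant 1 it was 0.28, and it was 0.46 with median-of-ratios factors and 0.37 with quantile normalization.

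**Figure D1:**
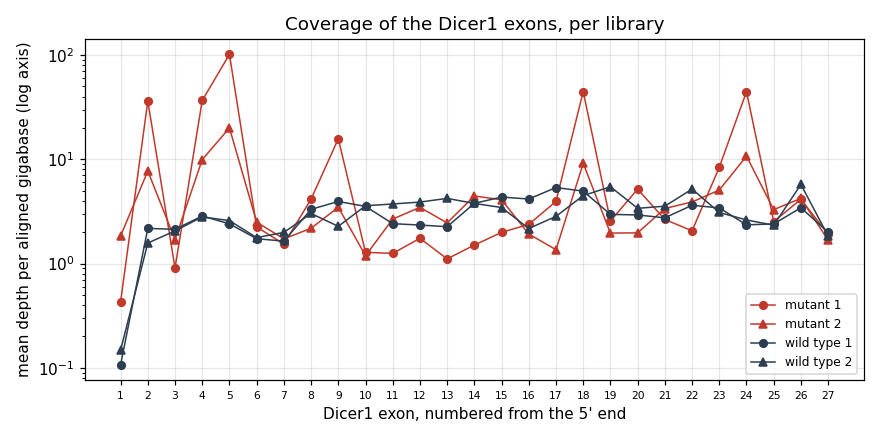
Mean read depth per aligned gigabase (log axis) over each of the 27 Dicer1 exons, numbered from the 5′ end, in the 4 libraries (red, mutants; dark, wild types; circles, number 1; triangles, number 2). Exons 2, 4, 5, 18 and 24 stand above both wild types in both mutants with a log2 ratio of at least 2, with depths of 102 and 20.03 in exon 5.

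The largest rises were in genes of the fetal liver. Igf2, a fetal growth factor, went from 0.803 and 0.408 TPM in the wild types to 6728 and 2556 TPM in the mutants, a log2 change of 11.90 with an SE of 0.48. Afp, the serum protein of the fetal liver, reached 2046 and 5782 TPM (log2 change 10.76, SE 0.49), and the imprinted long RNA H19 reached 16747 and 12474 TPM (log2 change 8.72, SE 0.26). Ly6d rose by 7.26 on the log2 scale, and Meg3 and Rian, long RNAs of the imprinted region on chromosome 12, by 7.21 and 7.13. Dlk1, from the same region, was at 101 and 14.1 TPM in the mutants and listed at 0 in both wild types. The epithelial genes Tff3 and Sprr1a rose by 6.84 and 6.59, with most of the level in mutant 2 (301 against 28.2 TPM for Tff3, 204 against 31.6 TPM for Sprr1a). Krt20, a keratin of simple epithelia, was at 16.5 and 97.8 TPM in the mutants and at 0 in both wild types. For the 10 genes with the largest rises, limma's Benjamini-Hochberg adjusted p was between 0.00223 and 0.0214.

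The largest falls were in the major urinary proteins, pheromone carriers secreted by the liver, and in the organic anion transporter Slco1a1. Summed over 22 Mup genes, the family was at 592 and 13 TPM in the mutants against 10523 and 15675 TPM in the wild types (log2 change -7.17, SE 1.69; limma, Benjamini-Hochberg adjusted p = 0.0400). Mup22, Mup10, Mup11, Mup9, Mup1, Mup8, Mup13, Mup7 and Mup2 made up 9 of the 10 largest falls by the naming rule. These copies are nearly identical and share reads, so the value of each member is uncertain and the family sum, formed after the values were seen, is the safer measure. Slco1a1 went from 80.3 and 67.0 TPM to 0.218 and 0 TPM (log2 change -6.95, SE 0.25; limma, Benjamini-Hochberg adjusted p = 0.00223).

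Of the 14792 genes tested, 2538 were higher and 500 lower in the mutants (limma, Benjamini-Hochberg adjusted p below 0.05, two-sided), and 1876 and 399 of these changed by at least 1 on the log2 scale. The groups did not overlap in 70.7% of the genes, where chance gives 33.3% if no shift is shared by all genes. The median log2 difference was 0.303 between the mutants and 0.186 between the wild types. The shift of all genes given next is larger and can by itself part the groups in many genes. The median log2 change of all genes was 0.38 and the calls were 83.5% higher; with median-of-ratios factors the median was 0.00 and 52.9% of the calls were higher (941 higher and 837 lower), so the direction of a small change depends on the scaling, and group medians below are read against 0.38. No gene passed without wild type 1 (3195 at an unadjusted p below 0.05) or without wild type 2 (3289 at an unadjusted p below 0.05) in the same limma fit, where the spread comes from the mutant pair alone. Without mutant 1 the limma fit called 3112 genes higher and 807 lower, and without mutant 2 it called 894 higher and 346 lower.

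**Figure D2:**
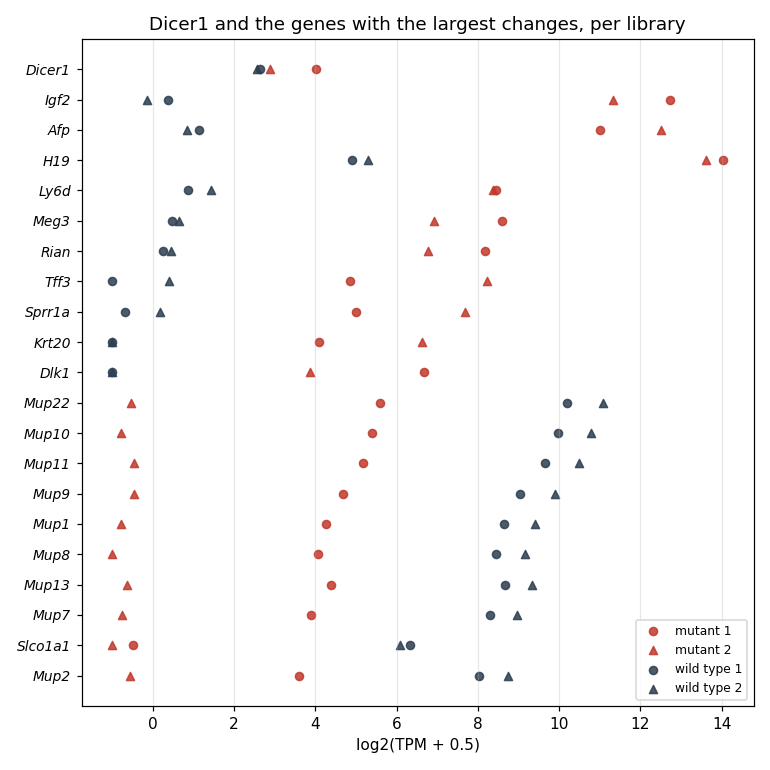
Level of Dicer1 and of the 10 genes with the largest rises and the 10 with the largest falls, as log2(TPM + 0.5), 1 point per library (red, mutants; dark, wild types; circles, number 1; triangles, number 2). Igf2 reached 6728 and 2556 TPM in the mutants; mutant 2 lies below mutant 1 in each Mup gene drawn.

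Among gene lists written before the data were examined, those of fetal and biliary genes were higher and those of adult hepatocyte functions lower. Among fetal liver and oncofetal genes, 15 of 19 rose and none fell (16 rose when adjusted over the list alone), with a median log2 change of 4.60. Gpc3, a fetal cell-surface proteoglycan, rose by 5.04 with an SE of 0.19. The list stood above other genes by limma's camera test (Benjamini-Hochberg adjusted p = 3.21e-08; adjusted p = 0.272 with an estimated correlation). Among markers of cholangiocytes, the cells that line bile ducts, 18 of 23 rose and none fell (18 adjusted over the list alone), with a median of 2.69. Krt23 rose by 4.42, the tight junction genes Cldn7 and Cldn4 by 5.29 and 4.70, and the membrane protease St14 by 3.38. For this list camera gave an adjusted p of 5.78e-08 (limma, Benjamini-Hochberg), and adjusted p = 0.376 with an estimated correlation. With median-of-ratios factors 14 fetal and 16 biliary genes were higher, and with quantile normalization 13 and 15.

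Cholesterol biosynthesis was the list with the smallest p by camera. Of its 24 genes 19 fell and none rose (22 adjusted over the list alone), with a median of -1.67 and medians of -1.58 and -1.54 in the 2 mutants taken singly. Cyp51 fell by 2.66, Msmo1 by 2.51, the HMG-CoA synthase Hmgcs1 by 2.16 and Nsdhl by 1.96 on the log2 scale, each with an SE of 0.16 to 0.21. Camera gave an adjusted p of 2.39e-28 (limma, Benjamini-Hochberg), and adjusted p = 0.272 with an estimated correlation. Fatty acid and triglyceride synthesis had a median of -0.44, with 5 of 23 genes lower and 1 higher (5 and 1 adjusted over the list alone). Elovl5, an elongase of polyunsaturated fatty acids, fell by 1.81, and the citrate lyase Acly by 1.08. Fatty acid oxidation and PPARA targets had a median of -0.50, with 8 of 25 genes lower and 1 higher (10 and 1 adjusted over the list alone). In that list Cyp4a14 fell by 3.48, the fatty acid binding protein Fabp1 by 2.16 and the peroxisomal thiolase Acaa1b by 1.55. Both lists were lower by camera (limma, Benjamini-Hochberg adjusted p = 3.21e-08 and 1.26e-10), and adjusted p = 0.272 for each with an estimated correlation. With median-of-ratios factors 21 cholesterol, 5 fatty acid synthesis and 12 fatty acid oxidation genes were lower, and with quantile normalization 21, 4 and 7.

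Cytochrome P450 and drug metabolism genes had a median of -0.97, with 10 of 32 lower and 3 higher (11 and 3 adjusted over the list alone). The median was -0.38 in mutant 1 and -1.40 in mutant 2. Cyp2c50 fell by 2.90, Cyp2c37 by 2.19, Cyp2c38 by 3.82 and Cyp2a4 by 2.66; these enzymes have close paralogs, which can share reads. Bile acid synthesis and transport had a median of -0.52, with 5 of 25 genes lower and 3 higher (5 and 3 adjusted over the list alone). The members that rose included Slc51b (3.02) and Abcc4 (3.01), which export bile acids and other anions from the basolateral side. The members that fell included Slco1a1 and Slco1a4 (-1.26), which take up organic anions. The bile acid median was -0.32 in mutant 1 and -0.62 in mutant 2. Both lists were lower by camera (limma, Benjamini-Hochberg adjusted p = 1.83e-12 and 1.12e-06), with adjusted p = 0.376 and 0.272 with an estimated correlation. With median-of-ratios factors 10 P450 genes were lower and 1 higher, and 6 bile acid genes lower and 2 higher. With quantile normalization the counts were 6 lower and 2 higher, and 2 lower and 2 higher.

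Hepatocyte identity and secreted protein genes had a median of -0.44, with 5 of 24 lower and none higher (5 adjusted over the list alone). Apoa2 and Apoc3, apolipoproteins, fell by 1.37 and 1.18. Albumin (Alb), named here outside the rule because it is the most abundant hepatocyte product, was at 75269 TPM in the mutants and 108396 TPM in the wild types, a log2 difference of -0.55 with an SE of 0.46 that did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.405). Pericentral genes, expressed around the central vein, had a median of -0.55, with 6 of 20 lower and 1 higher (6 and 3 adjusted over the list alone); Aldh1a1 fell by 2.26 and Gstm3 rose by 3.97. Periportal genes had a median of -0.39, with 6 of 20 lower and 1 higher (6 and 1 adjusted over the list alone); the histidase Hal fell by 2.23 and the cadherin Cdh1 rose by 2.01. Urea cycle and amino acid catabolism had a median of -0.39, with 6 of 25 lower and none higher (6 adjusted over the list alone); Arg1 fell by 0.94 and Prodh by 2.06. Complement and coagulation had a median of -0.44, with 3 of 31 lower (2 adjusted over the list alone), and medians of -0.12 in mutant 1 and -0.59 in mutant 2; C8a and C8g, which encode chains of complement component C8, fell by 1.07 and 1.18. Gluconeogenesis and glycolysis of the adult liver had a median of -0.23, with 3 of 16 lower (3 adjusted over the list alone), and medians of -0.10 in mutant 1 and -0.45 in mutant 2; the ketohexokinase Khk fell by 1.59 and the pyruvate kinase Pklr by 1.40. These 6 lists were lower than other genes by camera (limma, Benjamini-Hochberg adjusted p between 9.01e-10 and 5.57e-05), and adjusted p was between 0.272 and 0.475 with an estimated correlation. The medians of the other 4 lists lay between -0.26 and -0.32 in mutant 1 and between -0.51 and -0.74 in mutant 2. With quantile normalization the calls of hepatocyte identity, periportal and gluconeogenesis genes ended (limma, Benjamini-Hochberg adjusted p = 0.0528, 0.0519 and 0.0801), and 3 hepatocyte identity, 2 periportal and 2 gluconeogenesis genes passed as lower. Pericentral, urea cycle and complement genes then had 5, 3 and 2 lower. With median-of-ratios factors 7 hepatocyte identity, 6 pericentral, 6 periportal, 9 urea cycle, 5 complement and 3 gluconeogenesis genes were lower.

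Lists of female-biased and of male-biased liver genes were both lower in the mutants, and all mice were female by Xist and the Y-linked genes. Of 18 female-biased genes 6 fell and none rose (8 adjusted over the list alone), with a median of -2.75; Hao2 fell by 2.84, and Sult3a1 was at 6.31 and 8.76 TPM in the wild types and listed at 0 in both mutants. Of 15 male-biased genes 9 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of -2.16; Hsd3b5 fell by 3.64 and Cyp2d9 rose by 2.12. Both lists were lower by camera (limma, Benjamini-Hochberg adjusted p = 1.26e-10 for each), with adjusted p = 0.361 and 0.376 with an estimated correlation. The female-biased median was -1.22 in mutant 1 and -3.01 in mutant 2, and the male-biased median -1.49 and -2.84. With median-of-ratios factors 6 female-biased and 8 male-biased genes were lower, and with quantile normalization 5 and 4. The male-biased list holds Mup genes and Slco1a1, already described.

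Among markers of other liver cells, those of stellate cells, macrophages and neutrophils were higher. Of 34 genes of stellate cells, fibroblasts and extracellular matrix, 29 rose and none fell (31 adjusted over the list alone), with a median of 1.60; Timp1, an inhibitor of matrix proteases, rose by 4.33, Col6a3 by 2.38 and the crosslinking enzyme Loxl1 by 2.17. Of 24 genes of Kupffer cells, monocytes and macrophages, 15 rose and none fell (21 adjusted over the list alone), with a median of 1.53; the monocyte chemokine receptor Ccr2 rose by 2.94 and Cd14 by 2.84. Of 11 genes of neutrophils, 6 rose and none fell (9 adjusted over the list alone), with a median of 1.69; S100a9 rose by 2.70 and Lcn2, which hepatocytes also secrete, by 4.59. These 3 lists were higher by camera (limma, Benjamini-Hochberg adjusted p = 1.50e-08, 5.00e-06 and 0.00115), with adjusted p = 0.475, 0.376 and 0.376 with an estimated correlation. Of the stellate list 13 genes passed with median-of-ratios factors and 13 with quantile normalization, of the macrophage list 12 and 12, and of the neutrophil list 6 and 3. Endothelial markers had a median of 0.18, below that of all genes and of the opposite sign with median-of-ratios factors (-0.21); Cd34 rose by 2.08 and the sinusoidal marker Lyve1 fell by 0.74, the 2 of 21 genes past the test (1 higher and 0 lower adjusted over the list alone), and the list was not called by camera or fry (limma, Benjamini-Hochberg adjusted p = 0.177 and 0.449). Lymphocyte markers had a median of 0.56 (0.70 in mutant 1 and 0.35 in mutant 2) with 4 of 20 higher (4 adjusted over the list alone), but 0 with median-of-ratios factors or quantile normalization, and were called by neither camera nor fry. Of 9 erythroid genes none passed in either direction (0 adjusted over the list alone), but the list was lower than other genes by camera, with a median of -0.11 (limma, Benjamini-Hochberg adjusted p = 0.0322; adjusted p = 0.376 with an estimated correlation, and 0.0706 with median-of-ratios factors). Mesothelial markers had a median of 0.44 (-0.10 with quantile normalization), with 0 of 6 genes past the test (0 adjusted over the list alone), and were called by neither camera nor fry. Too few genes were measured to test markers of exocrine pancreas, gallbladder and adipocytes: Cela1 fell by 1.39, Tff2 was at 5.76 and 1.67 TPM in the mutants and 0 in both wild types, and Car3, abundant in hepatocytes too, fell by 3.10.

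Of the lists of inflammation, stress and signalling genes, those of NF-kB cytokines, p53 targets and YAP targets were higher. The list of immediate early genes, fixed among the technical checks, was higher as well, and the cause was not tested. As written, it shares Btg2 with the p53 list, Atf3 with the unfolded protein list and Myc with the Wnt target list. Of 20 NF-kB cytokine and chemokine genes 13 rose (18 adjusted over the list alone), with a median of 1.57; Relb rose by 2.94, the NF-kB feedback gene Tnfaip3 by 2.15 and Cxcl16 by 2.20. Of 26 p53 target and DNA damage genes 13 rose (19 adjusted over the list alone), with a median of 0.98; Gadd45b rose by 3.11, Pmaip1 by 2.08 and Phlda3 by 1.96. Of 19 targets of the Hippo effector YAP 13 rose (15 higher and 1 lower adjusted over the list alone), with a median of 1.16; Ccn2 rose by 2.81, Ccn1 by 2.21 and Ajuba by 2.16. Of 17 immediate early genes 9 rose (12 adjusted over the list alone), with a median of 1.22; Jun rose by 2.20 and Myc by 2.16. These 4 lists were higher by camera (limma, Benjamini-Hochberg adjusted p between 4.00e-05 and 0.00501), with adjusted p between 0.288 and 0.475 with an estimated correlation. With median-of-ratios factors 9 NF-kB, 8 p53, 7 YAP and 8 immediate early genes were higher, and with quantile normalization 8, 6, 4 and 7. The unfolded protein and integrated stress response list was lower by camera with a median of -0.22 (-0.36 in mutant 1 and -0.11 in mutant 2) but a mean of 0.33. Camera's adjusted p was 0.0159 (limma, Benjamini-Hochberg), 0.624 with an estimated correlation, and 0.0678 with median-of-ratios factors. Of its 21 genes 3 rose, among them the asparagine synthetase Asns (5.02) and Atf3 (2.30), and the chaperone partner Sdf2l1 fell by 1.13 (3 and 1 adjusted over the list alone). With median-of-ratios factors 2 were higher and 4 lower, and with quantile normalization 2 and 1.

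Both lists of cell cycle genes were higher, with larger medians in mutant 2. Of 34 genes of G2, M phase and mitosis 23 rose and none fell (34 adjusted over the list alone), with medians of 1.55 in mutant 1 and 2.72 in mutant 2. Cdk1 was at 6.40 and 12.8 TPM in the mutants and at 1.34 and 0.962 TPM in the wild types, and Top2a rose by 2.27. Of 30 genes of the G1 to S transition and DNA replication 17 rose (25 adjusted over the list alone), with medians of 0.92 and 1.83; Uhrf1 rose by 2.41 and the helicase subunit Mcm6 by 1.94. Both lists were higher by camera (limma, Benjamini-Hochberg adjusted p = 7.86e-07 and 0.000531), with adjusted p = 0.607 and 0.628 with an estimated correlation. Fewer of these genes passed under other scalings: 13 of G2, M phase and mitosis and 8 of G1 to S with median-of-ratios factors, and 4 and 2 with quantile normalization. Cytoplasmic ribosomal protein genes had a median of 0.57, with 0.36 in mutant 1 and 0.81 in mutant 2, and with 2 of 30 higher (0 adjusted over the list alone). They were called higher by camera (limma, Benjamini-Hochberg adjusted p = 0.0152, and 0.680 with an estimated correlation). The camera call ended with median-of-ratios factors (adjusted p = 0.0678) but held with quantile normalization (adjusted p = 6.86e-09, median 0.67).

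Of the 5 lists of cilia genes, camera called cilia disassembly higher, and fry, which asks whether the genes of a list move 1 way from 0 on balance, called 3 others higher on a scale where all genes had a median of 0.38. Genes of cilia disassembly and the centrosome cycle had a median of 0.68 with 4 of 17 higher (8 adjusted over the list alone); Nedd9 rose by 2.28, and the mitotic genes Tpx2 and Plk4 by 2.36 and 1.57. That list was called higher by camera (limma, Benjamini-Hochberg adjusted p = 0.0363). Its camera adjusted p was 0.635 with an estimated correlation and 0.0534 with quantile normalization. As written, the cilia disassembly list shares Aurka, Plk1 and Tpx2 with the list of G2, M phase and mitosis. Its call is thus not independent of the rise of cell cycle genes. Intraflagellar transport genes had a median of 0.57 with 8 of 28 higher (9 adjusted over the list alone), and the list was called by fry (limma, Benjamini-Hochberg adjusted p = 0.0269) but not by camera (0.0561); Dync2li1 rose by 2.60 and Ift57 by 1.73. Transition zone and BBSome genes had a median of 0.58 with 5 of 38 higher (4 adjusted over the list alone), genes of polycystic liver and kidney disease 0.50 with 4 of 19 (6 adjusted over the list alone), and motile cilia genes 0.87 with 1 of 7 (3 adjusted over the list alone), and these 3 lists were not called by camera. By limma's fry the Benjamini-Hochberg adjusted p was 0.0378 for transition zone and BBSome genes, 0.0321 for polycystic disease genes, 0.114 for motile cilia and 0.0920 for cilia disassembly. Under other scalings fewer cilia genes passed: 4 of intraflagellar transport, 3 of the transition zone, 1 of polycystic disease and 2 of disassembly with median-of-ratios factors, and 2, 1, 1 and 1 with quantile normalization. The medians of intraflagellar transport, transition zone and polycystic disease genes came to 0.19, 0.21 and 0.12 with median-of-ratios factors and to 0.04, 0.03 and 0.13 with quantile normalization. The motile cilia median was 0.24 in mutant 1 and 1.32 in mutant 2. Foxj1, the regulator of motile cilia, rose by 2.46, and Bicc1, a gene of cystic kidney, by 3.21.

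In the main fit camera called none of the following lists. It placed Wnt target, acute phase, endothelial and mitochondrial genes below other genes although their medians lay above 0. With quantile normalization it called NRF2 targets and glycolysis genes of proliferating cells higher (limma's camera, Benjamini-Hochberg adjusted p = 0.0415 and 0.00358). Hedgehog pathway genes had a median of 0.81 with 4 of 11 higher and 1 lower (8 and 1 adjusted over the list alone): the ligand Ihh rose by 2.59 and the co-receptor Gas1 fell by 1.98. Notch pathway genes had a median of 0.60 with 4 of 17 higher (9 adjusted over the list alone), among them Hes1 (1.88) and Sox9 (1.86). Wnt target genes had a median of 0.33 with 3 of 19 higher and 1 lower (4 and 1 adjusted over the list alone), and their median changed sign with median-of-ratios factors (-0.05). Acute phase genes had a median of 0.34, which also changed sign (-0.07), with 6 of 22 higher and 2 lower (8 and 4 adjusted over the list alone); Saa3 rose by 2.12 and Serpina3m fell by 2.11. Interferon-stimulated genes had a median of 0.51 (0.96 in mutant 1 and 0.15 in mutant 2) with 4 of 25 higher (1 adjusted over the list alone), and NRF2 targets 0.95 (0.35 and 1.57) with 3 of 19 higher and 1 lower (6 and 1 adjusted over the list alone). Glycolysis genes of proliferating cells had a median of 0.86 with 6 of 19 higher and 1 lower (9 and 1 adjusted over the list alone). Circadian genes had a median of -0.06 and a mean of 0.23, with Per1, which rose by 2.32, as the 1 gene of 15 past the test (1 adjusted over the list alone). Mitochondrially encoded transcripts had a median of 0.01, or -0.40 with median-of-ratios factors, with 0 of 13 past the test (0 adjusted over the list alone). Fry called the Hedgehog, Notch and Wnt target lists higher (limma, Benjamini-Hochberg adjusted p = 0.0321, 0.0204 and 0.0112), again from 0; with median-of-ratios factors the Hedgehog and Notch medians were 0.50 and 0.22, and with quantile normalization 0.24 and 0.12. With median-of-ratios factors 2 Hedgehog, 2 Notch, 1 Wnt target, 3 acute phase, 0 interferon, 2 NRF2 and 2 glycolysis genes were higher, and with quantile normalization 1, 2, 1, 5, 0, 3 and 2. The counts of lower genes in the same order were 1, 1, 1, 4, 0, 1 and 1 with median-of-ratios factors, and 1, 0, 1, 2, 0, 1 and 1 with quantile normalization. More acute phase genes were thus lower than higher with median-of-ratios factors.

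**Figure D3:**
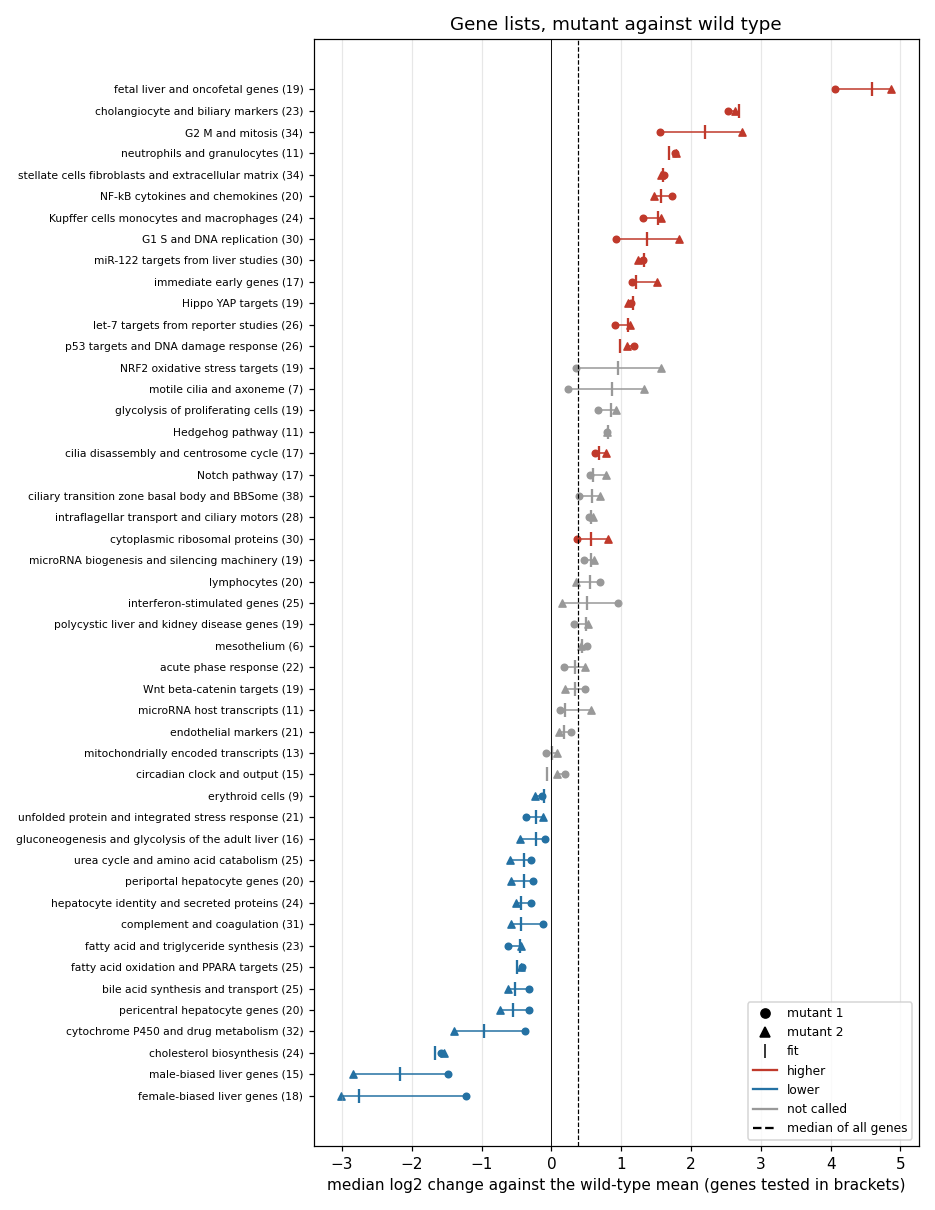
Median log2 change of each of the 48 tested gene lists against the wild-type mean, for mutant 1 (circles) and mutant 2 (triangles), with the median of the fitted changes as a tick (red, higher by camera; blue, lower; grey, not called by camera; dashed line, median of all genes at 0.38). Fetal liver and oncofetal genes lie highest at 4.60, and female-biased liver genes lowest at -2.75.

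In all, 15 of 48 lists were higher and 15 lower by camera with the preset correlation of 0.01. Some lists share genes, so these counts are not of independent results. The periportal and urea cycle lists share Hal and Arg1, the pericentral and P450 lists Cyp2c37 and Cyp2c50, and the female-biased and P450 lists Cyp2a4. With a correlation estimated from these 4 libraries, camera called 0 lists (7 at an unadjusted p below 0.05, smallest adjusted p = 0.272), and limma's directional fry test called 19 higher and 5 lower. The lost calls do not rest on the correlation alone, since that camera run also has few degrees of freedom. For miR-122 targets the estimated correlation was -0.032, below the preset 0.01, yet camera's unadjusted p went from 1.74e-07 to 0.0272. The 5 lower lists by fry were cholesterol biosynthesis, bile acid genes, fatty acid oxidation, hepatocyte identity and pericentral genes. Both cell cycle lists, cilia disassembly and ribosomal proteins, called higher by camera, were not called by fry.

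Genes with sites for miR-122, the most abundant microRNA of hepatocytes, were higher in the mutants. The 3′ UTR 7-mer ACACTCC, which pairs with the miR-122-5p seed, had the highest z of all 7-mers (z = 6.56). At the other end of the ranking, 7-mers of no listed microRNA reached larger absolute values, with z = -7.85 for GTTCAAT, -6.86 for CAGCATC and -6.62 for TACAGCA. Next to shifted forms of the miR-122 site, such as CACTCCA (z = 5.16), T-rich 7-mers stood high as well, among them TTTTTTA (z = 4.78) and TTTTTTT (z = 4.62). The median log2 change was 0.60 in the 1113 genes with the site and 0.39 in the 11367 genes without it. The let-7-5p site CTACCTC had z = 1.70 and rank 294, the miR-30-5p site z = 1.85 and rank 204, and the miR-101-3p site z = 1.95 and rank 163. The miR-130-3p site had the lowest z of the listed sites, at -3.53. Its unadjusted medians went the other way, with 0.432 in genes with the site and 0.401 in genes without it. The 11 sites of 5p strands had a mean z of 0.854 ± 2.13 (SD) and the 10 sites of 3p strands a mean of -0.303 ± 1.57 (SD). The difference of 1.16 did not pass a two-sided permutation test of the strand labels with 100000 resamples (p = 0.184). Without the miR-122 and let-7 sites, left out after their values had been seen, the mean of the 9 other 5p sites was 0.126 and the difference 0.429 (permutation p = 0.499).

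Lists of genes named as miR-122 and let-7 targets in earlier studies were higher as well. These lists overlap others described above and are not independent of them. As written, the let-7 list shares genes such as Hmga2, Igf2bp3 and Lin28b with the fetal list. The miR-122 list shares Sox4 and Prom1 with the biliary list, Ccl2 with the NF-kB list and Aldoa with the glycolysis list. Of 30 miR-122 targets 22 rose and none fell (26 adjusted over the list alone), with a median of 1.33; the glycolytic enzyme Aldoa rose by 2.58, Klf6 by 2.20 and Agpat1 by 2.12. Of 26 let-7 targets 15 rose and none fell (18 adjusted over the list alone), with a median of 1.10; the phosphatase Cdc25a rose by 3.01, Nr6a1 by 1.97 and Tgfbr1 by 1.96. Both lists were higher by camera (limma, Benjamini-Hochberg adjusted p = 5.98e-07 and 0.000340), with adjusted p = 0.272 and 0.361 with an estimated correlation. With median-of-ratios factors 12 miR-122 and 8 let-7 targets were higher, and with quantile normalization 11 and 6. Genes of microRNA biogenesis and silencing had a median of 0.56 with 6 of 19 higher (6 adjusted over the list alone), but 2 with median-of-ratios factors and 1 with quantile normalization; Tnrc6a rose by 1.44 and Drosha by 1.14. MicroRNA host transcripts had a median of 0.20 (0.12 in mutant 1 and 0.56 in mutant 2) that changed sign with median-of-ratios factors (-0.11); 3 of 11 rose (3 adjusted over the list alone), among them H19 and Rian. Neither of these lists was called by camera (limma, Benjamini-Hochberg adjusted p = 0.0936 and 0.415), but fry called both higher than 0 (0.0235 and 0.0204); the biogenesis median was 0.18 with median-of-ratios factors and 0.14 with quantile normalization.

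**Figure D4:**
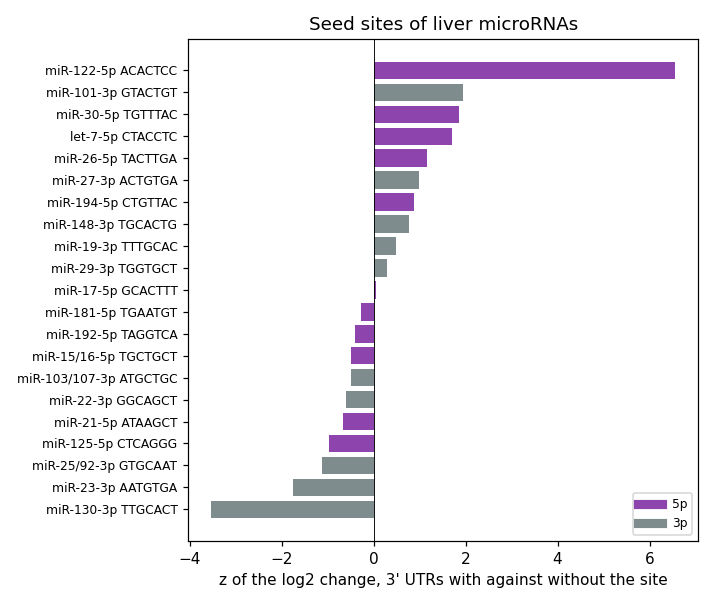
z of the log2 change of genes whose 3′ UTR holds the seed site of each listed microRNA, against genes without it (bars start at 0; purple, 5p strands; grey, 3p strands). The miR-122-5p site stands at 6.56 and the miR-130-3p site at -3.53.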

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

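The tests of whole-gene transcription and of a diverged transcript for Dicer1, those of the share of the 20 most abundant genes and of other cell types for the split of calls, and those of GC content and base composition for single microRNA sites were chosen after the values they bear on had been seen; the others were set beforehand.

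Depth over single exons, which no test between groups uses, was above both wild types in both mutants, with a log2 ratio of at least 2, over 5 exons of Dicer1. The log2 ratios of mutant to wild-type mean depth were 3.24 in exon 2, 2.84 in exon 4, 4.36 in exon 5, 2.39 in exon 18 and 3.24 in exon 24. Exons 1, 6, 23 and 25 were also above both wild types in both mutants, with smaller log2 ratios of 1.38, 0.35, 0.94 and 0.25. Uneven coverage of long genes in the mutant libraries is argued against, since 0.052% of 3812 other genes with at least 10 exons (Ces3b and Klhl13) had a spread of exon ratios as large as that of Dicer1, and so is more transcript of the whole gene, since the other exons had a median log2 ratio of -0.17. A candidate explanation that stays open is a Dicer1 transcript of diverged sequence, such as one from a construct of another species, that aligns in its most conserved exons alone. The excess over exons had a Pearson r of 0.959 between the mutants, but the rise of the same exons in both had been seen before, so this r decides nothing. An aberrant splice form of the gene itself would give the same value, no other species' sequence was used here, and the genotype is the biological explanation in the design.

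More genes were called higher than lower, 83.5% of the calls. Rescaling without the 20 most abundant genes left 84.4% higher, but decides nothing, since it moved the median change of all genes only from 0.38 to 0.39. The 20 most abundant genes of each library took 36.8% to 37.9% of its TPM. This argues against a smaller total share of each library's own 20 most abundant genes as the source of the split. The share outside them differed between the groups by 0.012 on the log2 scale (SD within a group up to 0.014), where the median change of all genes was 0.38. The 20 genes were taken per library, so a gene that rose can replace one that fell. Loss of the genes most abundant in the wild types was not measured by this share. With median-of-ratios factors 52.9% were higher, but these factors centre the changes at 0 and so bring the split near even by construction; whether the liver holds more transcript of most genes or fewer of a wider set of abundant ones cannot be told apart from relative values. A gain of every other cell type alike is argued against, since the endothelial median lay 1.35 below the lower of the stellate and macrophage medians. The SD over genes was 0.578 in the endothelial, 0.821 in the stellate and 1.01 in the macrophage list. Marker levels were measured and cell numbers were not, and the stellate list also holds extracellular matrix genes, so the argument is limited. A gain of stellate cells and macrophages, and the genotype itself, stay open.

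Genes with a miR-122-5p site were higher, and for miR-122 and let-7 sites together the mean z was 4.13. The planned test of base composition, on the mean of both sites, put them 3.36 above their reverse complements, but miR-122 carries this gap, so the sites are taken singly. For miR-122, GC content and base composition are argued against. Its site had a z 5.87 above that of its reverse complement, which shares the GC content. That z was also 7.02 above the mean of 102 7-mers with the same bases in another order (SD 1.30, highest z 2.30). Reorderings that are shifted forms of the site, such as CACTCCA (z = 5.16), were left out of the 102. For let-7 both stay open, with gaps of 0.851 and 1.91, each within the limit of 2. The reordered 7-mers for let-7 still held some that contain CACTCC of the miR-122 site, such as CACTCCT (z = 4.98) and TCACTCC (z = 3.18). These raise the mean of the reorderings and so narrow the gap of 1.91. Other cell types that express the targets stay open: without cell type markers and without genes raised by more than 2 on the log2 scale the mean z was 3.53, but this may leave in most genes of the cells whose markers rose, with medians of 1.60 and 1.53 in the stellate and macrophage lists. The same 7-mers in the coding sequence had a mean z 1.15 below that in the 3′ UTR, within the limit of 2 planned for the mean. Taken singly, the let-7 site was at 1.83 in the coding sequence against 1.70 in the 3′ UTR. The miR-122 site was at 4.12 against 6.56, a gap wider than 2, so the mean hides a difference between the sites. Since 4.12 is itself high, a property of the genes that hold the site, codon use included, stays open. It stands beside loss of microRNA action by genotype. Coding sites can respond to a microRNA too, and miR-122 accounts for most of the mean (6.56 against 1.70 for let-7).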

How the results depend on the processing

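The counts of calls moved with the scaling, the filter and the libraries. Voom on estimated reads, nuclear protein-coding genes alone and the site comparison without miR-122 and let-7 were added after the data had been seen. Without the filter 565 genes were higher and 138 lower, with 23058 genes tested; quantile normalization gave 688 higher; median-of-ratios factors gave 941 higher and 837 lower; an adjusted p of 0.10 gave 4462 and 825. Leaving out 1 library gave 0 to 3112 higher and 0 to 807 lower genes, with 0 for each without wild type 1 or wild type 2; without mutant 2, 894 were higher. In these fits the lone sample is assumed to vary like the other group, so the 0 without a wild type rests on the spread between the mutants, which is wider (median difference 0.303 on the log2 scale, against 0.186 between the wild types). The other alternatives kept both counts within 1.5 times; of the main calls, 941 of 2538 higher and 489 of 500 lower genes were also called with median-of-ratios factors. With the replicate number as a replicate block, 2261 genes were higher and 472 lower. The deviations of same-numbered samples had a correlation of -0.075, so no effect shared by same-numbered samples was seen. A small one could be missed, so this value cannot show whether the numbers pair the mice.

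For gene lists, camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 5 lower. That camera run has few degrees of freedom, so it does not show that correlation among genes removed the calls. Leaving out 1 library gave 13 to 16 higher and 14 to 17 lower by camera with the preset correlation. By fry the Wnt target list moved up on balance (median 0.33, adjusted p = 0.0112), where camera placed it below other genes without a call, and the unfolded protein list was turned from lower to an uncalled higher (median -0.22, adjusted p = 0.492). Both differences follow from what fry tests, since it does not compare with other genes. The Dicer1 difference stayed above 0 in each alternative run, with 0.28 to 1.41 when 1 library was left out. The difference between 5p and 3p sites passed in no alternative; it was 0.965 to 1.28 over the planned ones (0.965 to 1.28 when 1 library was left out) and 0.429 without the miR-122 and let-7 sites (permutation p = 0.499), so much of it rests on these sites. Of 199 genes named by the rule other than Dicer1, 170 were called in the main fit, and none of these turned its direction under the alternatives run. Of the 170, 99 lost the call without the filter, 49 with quantile normalization and 31 with median-of-ratios factors. Leaving out either wild type ended all of these calls, and leaving out a mutant ended some. Apart from the construction named above, the cause was not tested. Depth limits values near 0.0487 to 0.0606 TPM, where 1 pair decides.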

Other observations

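The 4 gene families and the 2 single genes below were chosen after their values had been seen, while the test of imprinted genes was set before its result. Annexins, which bind membranes in the presence of calcium, were mostly higher in the mutants: 8 of 10 rose and none fell, with a median log2 change of 1.24 (0.84 to 1.31 over the scalings run). Anxa2 rose by 2.89 and Anxa5 by 2.56. Of 9 keratins, the intermediate filament proteins of epithelia, 6 rose and none fell, with a median of 2.47 (1.97 to 2.50 over the scalings run). Krt8 was at 608 and 1606 TPM in the mutants and at 126 and 218 TPM in the wild types, and its partner Krt18 rose by 2.51; Krt7, Krt19 and Krt23, also raised, belong to the biliary list. Carboxylesterases, which hydrolyse lipid and drug esters, went both ways, with 5 of 13 lower and 2 higher and a median of -1.41 (-1.80 to -1.37 over the scalings run). Ces3b (-6.10 on the log2 scale), Ces3a (-3.63) and Ces1d (-2.76) fell, whereas Ces2c rose by 1.71. Of 15 glucuronosyltransferases 6 fell and none rose, with a median of -1.21 (-1.62 to -1.20 over the scalings run), among them Ugt1a5, which fell by 3.65, and Ugt2a3, which fell by 2.42. Members of the last 2 families are close copies, and the Ugt1a transcripts share exons, so the values of single members are uncertain. The aldose reductase family member Akr1b7 rose by 5.99 and the paraoxonase Pon1 fell by 3.95. For the genes named here limma's Benjamini-Hochberg adjusted p was below 0.05; the families themselves were not tested.

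The rises of Igf2, H19, Dlk1, Meg3 and Rian, which are imprinted genes, led to the hypothesis that imprinted genes respond as a class. Of 46 imprinted genes outside the fixed lists 34 were measured well enough to test; 9 rose and none fell, with a median log2 change of 0.49 where all genes had 0.38. The growth factor receptor adaptor Grb10 rose by 4.19 with an SE of 0.17, Phlda2 by 3.06, Usp29 by 2.20 and the IGF2 receptor Igf2r by 1.92. As a class they did not stand above other genes (limma's camera, p = 0.144; p = 0.37 with an estimated correlation), so the hypothesis was not borne out beyond these members.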
